A study of Homo sapiens with 6 samples.

How the data were processed

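Total RNA of HeyA8-MDR cells treated with siControl (3 arrays) or siGRAMD1B (3 arrays) was amplified to biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. Signals were exported with BeadStudio, per the submitters' processing notes, whose version is not given in the sources used here. The deposited non-normalized table holds an intensity on a linear scale for each of 47231 probes and 6 arrays. Its values were neither normalized between arrays nor background-subtracted as far as they show, since the medians of the arrays differed and the lowest value was above 70 on each. The labels speak of an export per gene, but the rows are probes. The header of that table holds 1 name more than there are fields with values, so the names of the 6 arrays stand 1 field to the right of their values and were shifted back. The assignment was checked against the second deposited table, in which the column of the same array ranked the probes alike (Spearman's rho 1.00 across probes, which are not independent replicates), against at most 0.85 for any other array. That second table holds the authors' log2 values, which are normalized between arrays and share 1 distribution with a median of 6.86 in every column. They are not centred per gene, their direction is that of the intensities, and the authors' method of normalization is not given in the sources used here. No columns of other samples were present (0).

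Because the intensity table carried no detection p-values, the background was corrected by limma's normexp with an offset of 50, followed by quantile normalization and log2. Fold changes are therefore on the scale of log2 of the corrected intensity plus the offset, which understates the change of dim probes. Probes were tested if their mean log2 value lay above the 40th percentile, at 6.16, which kept 28338. Each probe was tested with limma's lmFit and eBayes (2-sided), without a trend, array weights or covariates, and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. The moderated test had 17.9 degrees of freedom. Values are given as group mean ± SD over 3 arrays, and log2 differences with the standard error of the moderated fit. The design, the tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for 2 alternatives added later (an offset of 16, and a filter at the 70th percentile of mean values), the final form of the simulation, and those tests of explanations that are named as chosen after their results were seen. The design foresaw detection p-values and gave this background correction for the case that there were none.

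Gene symbols came from the platform annotation, in which 30113 probes had 1 symbol, 8 had several and 17110 were unnamed here. No symbol changed when updated through Entrez identifiers with the RefSeq gene table of the GRCh38.p14 assembly, in which 30074 of the probes were found. The tested probes with a symbol covered 14261 genes. The probes of a gene were tested separately, and in gene lists the probe with the highest mean stood for the gene. Called genes with another tested probe numbered 615, and in 86.3% of them the second probe had the same sign. Named genes were GRAMD1B, the 12 probes with the largest rise and the 12 with the largest fall among those past the threshold with all siGRAMD1B arrays on the same side of all siControl arrays, up to 4 members with the smallest p of each list described, and ABCB1. Probes without a gene name were counted but not named.

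The 31 gene lists covered sterol and fatty acid metabolism, drug response, cell fate, proliferation, immune signalling, RNA interference, cell state, stress, organelles, constitutive genes and other cell types. They were tested with camera at a preset inter-gene correlation of 0.01 (2-sided, Benjamini-Hochberg over the 31 lists, all with at least 5 measured members), and beside it with camera at an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. At an estimated correlation, camera also uses only the 4 residual degrees of freedom of the fit. A call lost there can come from this as well as from correlation between genes. Members were counted as higher or lower at an adjusted p under 0.05 over all probes, and again adjusted over the list alone. Fry's test for change in either direction passed for all 31 lists and is not used further.

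The procedure was tested on simulated data built from the probe means and spreads of these arrays, in which 200 of 28338 tested probes were given known changes in their signal above background. Among probes above the 75th percentile of mean values, 97.0% of 33 probes changed 3-fold, 78.8% of 33 changed 2-fold and 38.2% of 34 changed 1.5-fold were called. Among dimmer probes the shares were 36.4% of 33, 5.88% of 34 and 0% of 33. Their 3-fold changes, 1.58 on the log2 scale, were fitted with a median size of 0.54, rises and falls pooled. There were 4 false calls among 89. The simulated noise was independent between probes, and the 200 changed probes were fewer than the 2010 called in the real comparison. Since the adjusted threshold depends on that number, these shares need not hold for the real data. An earlier form of the simulation, in which the whole intensity was multiplied, was replaced after its result was seen, because a change of RNA level acts only on signal above background. A simulated list of 20 genes shifted by 0.4 on the log2 scale was found by camera, and an unshifted list of 20 was not. The simulated genes varied independently and shared the same shift, so this does not show how camera behaves with correlated members.

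Alternatives were no background correction, median centring or cyclic loess in place of quantile normalization, the deposited normalized values, other filters on dim probes, eBayes with trend and robust options, array weights, an ordinary equal-variance test per probe, the replicate number as a block, other thresholds, other set tests, and each array left out in turn. Analyses used R 4.3.3 with limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The siRNA sequences and the positions of the arrays on chips were not used here.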

Results

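HeyA8-MDR is a multidrug-resistant derivative of the human ovarian cancer cell line HeyA8. Its transcriptome was measured on Illumina bead arrays after treatment with a control siRNA (siControl) or with an siRNA against GRAMD1B (siGRAMD1B), which encodes an endoplasmic reticulum protein that carries sterols from the plasma membrane. Each group held 3 arrays, numbered 1, 2 and 4 for siControl and 2, 3 and 4 for siGRAMD1B. Every array gave an intensity for 47231 probes, with a median between 102.7 and 128.8 and a lowest value between 71.7 and 89.8, so that most probes lay close to the floor of the scale. The number of arrays limits the precision of every value. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The comparison asks how reducing GRAMD1B changes gene expression in drug-resistant cells. All log2 differences below are siGRAMD1B minus siControl.

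GRAMD1B itself was read by 1 probe (ILMN_3237376), which was lower in all 3 siGRAMD1B arrays than in every siControl array. Its normalized log2 intensity was 6.47 ± 0.09 in siControl (SD, n = 3) and 6.22 ± 0.05 in siGRAMD1B (SD, n = 3). The values per array were 6.42, 6.41 and 6.57 in siControl and 6.26, 6.23 and 6.17 in siGRAMD1B. The log2 difference of -0.25 ± 0.10 (SE) did not pass the threshold over all tested probes (limma adjusted p = 0.15). Unadjusted, for this 1 planned gene, the limma p was 0.020. Over the alternatives it ran from 0.0065 with the offset of 16 to 0.077 without siControl replicate 4. An exact 2-sided permutation test of the 6 arrays gave p = 0.10, the smallest value that 3 arrays against 3 allow. The siControl mean lay at the 62.9th percentile of all probes and the siGRAMD1B mean at the 48.7th, so the probe lay among dim probes in both groups, where the scale understates fold changes.

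Cells treated with siGRAMD1B had higher levels of inflammatory genes such as IL6, PTGS2 and CSF3 and lower levels of genes such as LRRC17, RACGAP1 and IDH1. At an adjusted p under 0.05, 1101 probes were higher and 909 were lower of the 28338 tested (limma). Of these, 295 were higher and 165 lower by at least 1.5-fold, and 48 were higher and 18 lower by at least 2-fold. With the ordinary test per probe 87 were higher and 43 lower by at least 1.5-fold and 11 lower by at least 2-fold, and with a lower background offset of 16, a setting chosen after the data were seen, 86 were higher by at least 2-fold. The called probes included 1699 with a gene symbol, from 857 genes that were higher and 618 that were lower, and no gene had called probes in opposite directions. All 209 genes with 2 or more called probes moved in 1 direction. Among all tested probes, 24.1% had the 3 arrays of a group entirely on the same side of the other 3, where chance gives 10%. With the offset of 16, 449 probes were higher and 234 lower, so that the share of higher probes among those called was 65.7% in place of 54.8%. Median centring in place of quantile normalization gave 603 higher and 419 lower, and the ordinary test per probe 164 and 92. With siControl replicate 1 left out, 741 probes were higher and 493 lower, and without each siGRAMD1B array in turn 673 to 695 were higher and 473 to 495 lower. Leaving out siControl replicate 2 gave 872 and 696, and leaving out siControl replicate 4 gave 1131 and 1007.

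The largest rise in the reported setting was that of KISS1, which encodes the precursor of kisspeptin, with 6.74 ± 0.28 in siControl and 8.87 ± 0.16 in siGRAMD1B (SD, n = 3), a 4.36-fold difference (log2 2.13 ± 0.13 SE, adjusted p = 1.61e-08). With no background correction, with the deposited normalized values and without siControl replicate 2, IL6 ranked above KISS1 (log2 1.90 against 1.78, 1.92 against 1.72 and 2.00 against 1.97). The cytokine gene IL6 followed at 3.90-fold (log2 1.96 ± 0.10 SE, adjusted p = 6.54e-09), from 9.36 ± 0.08 to 11.33 ± 0.13 (SD, n = 3). P2RY6, a receptor for pyrimidine nucleotides, was 3.39-fold higher and PTGS2, the inducible cyclooxygenase, 3.29-fold higher. GANAB, the catalytic subunit of the glucosidase that trims glycans in the endoplasmic reticulum, was 3.22-fold higher. The pseudogene ZNF702P rose 3.11-fold, and SDC4, a heparan sulfate proteoglycan of the cell surface, 3.06-fold. The mitochondrial superoxide dismutase gene SOD2 rose 2.90-fold, the scavenger receptor gene CD163L1 2.82-fold and 2.78-fold by its pair of probes, CSF3, which encodes granulocyte colony-stimulating factor, 2.81-fold, and ZBED2 2.80-fold. The siControl mean of ZBED2 (6.35) lay close to the array median of 6.27, so its fold and rank are uncertain. Its log2 difference of 1.49 ranged from 1.07 with the deposited normalized values to 2.04 with the offset of 16. KISS1, ZNF702P, PTGS2 and P2RY6 also started from low siControl means (6.74, 6.79, 6.97 and 6.99), so their folds depend on the setting too. Over the alternatives the log2 difference ran from 1.72 to 2.58 for KISS1 and from 1.29 to 2.01 for ZNF702P. The range was 1.41 to 2.05 for PTGS2 and 1.45 to 2.09 for P2RY6. By the rule that chose them, all 3 siGRAMD1B arrays exceeded all siControl arrays at each of these 12 probes. Their adjusted p-values, under 0.05 by the same rule, lay between 6.54e-09 and 4.43e-07. Further probes of P2RY6, SOD2 and CSF3 lay at the floor of the array, with mean log2 intensities of 6.20, 5.97 and 6.03, and showed log2 differences of 0.10, -0.04 and -0.07. A dimmer PTGS2 probe, with a mean of 6.60, was higher by 0.81 (adjusted p = 5.05e-05), against 1.72 for the probe given above.

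The largest fall was that of LRRC17, whose probes fell by 1.52 and 1.05 on the log2 scale. Its brighter probe went from 9.75 ± 0.18 in siControl to 8.23 ± 0.07 in siGRAMD1B (SD, n = 3, adjusted p = 7.99e-08). RACGAP1, a component of the central spindle needed for cytokinesis, fell by 1.31 (from 10.10 ± 0.14 to 8.79 ± 0.14, SD, n = 3, adjusted p = 4.94e-07), and its dimmer probe fell by 0.54 (adjusted p = 0.044). ANAPC11, the RING subunit of the anaphase-promoting complex, fell by 1.17 and TMEM250 by 1.16. IDH1, the cytosolic NADP-dependent isocitrate dehydrogenase, fell by 1.15, from 9.55 ± 0.10 to 8.40 ± 0.12 (SD, n = 3), with a further probe at -0.91. The RNA-binding protein gene IGF2BP3 fell by 1.14, and the nucleotide pyrophosphatase gene DCTPP1 by 1.10 and 1.07 at its probes. The phosphofructokinase gene PFKM fell by 1.09, the phosphatase gene PUDP by 1.07, and ZNHIT6, which takes part in the assembly of box C/D small nucleolar ribonucleoproteins, by 1.05. By the same rule, all 3 siGRAMD1B arrays lay below all siControl arrays at these 12 probes, with adjusted p-values between 7.99e-08 and 1.19e-05. Another LRRC17 probe, with a mean log2 intensity of 6.17, differed by -0.13, and 3 further ANAPC11 probes near the floor differed by -0.07, -0.04 and 0.00 while another fell by 0.81.

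**Figure D1:**
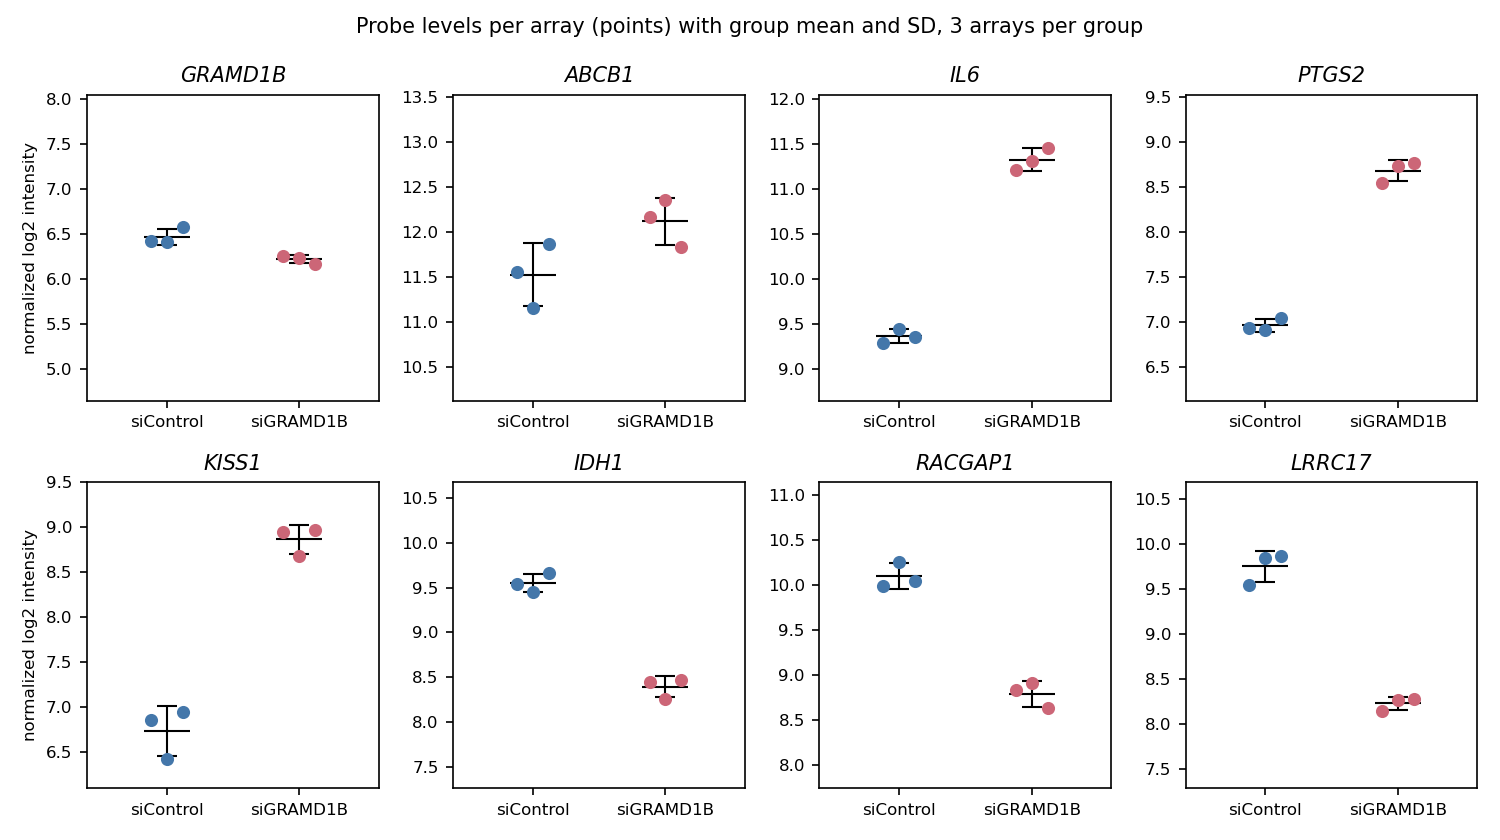
Normalized log2 intensity (vertical axis) of 8 probes in each of the 3 siControl arrays (blue points) and the 3 siGRAMD1B arrays (red points), with the group mean (long bar) and SD (capped bar). Every panel spans the same range of log2 units. IL6, PTGS2 and KISS1 were higher and IDH1, RACGAP1 and LRRC17 lower in all siGRAMD1B arrays, whereas the GRAMD1B probe differed by -0.25 near the floor and the ABCB1 values of the groups overlapped.

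In the list of NF-kB signalling and inflammatory cytokine genes, 13 of 21 measured members were higher, 0 were lower and 8 did not pass, with a median log2 difference of 0.43 (camera adjusted p = 7.55e-12). Camera at an estimated inter-gene correlation of 0.018, on 4 residual degrees of freedom, did not call the list (adjusted p = 0.073). Fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes, gave an adjusted p of 0.00084. Adjusted over the list alone, 17 were higher and 0 lower. IL6 and PTGS2 led the list, followed by CSF3 at 1.47 (adjusted p = 2.88e-07) and SOD2 at 1.45 (adjusted p = 4.00e-07), each by its brightest probe. Among JAK/STAT3 signalling genes, 3 of 20 were higher, namely STAT3 (0.75), the transcription factor gene CEBPD (0.66) and BCL3 (0.41), 0 were lower and 17 did not pass, and adjusted over the list alone 3 were higher and 1, SOCS1, was lower (log2 difference -0.34). The JAK/STAT3 list was not called as a group (median 0.02, camera adjusted p = 0.65). Interferon-stimulated genes had a median of -0.02 over 26 measured members, of which 0 were higher and 1, ISG20, was lower (-0.33, adjusted p = 0.045), with camera adjusted p = 0.80. Adjusted over the list alone, 0 interferon-stimulated genes were higher and 0 lower. Among genes of the RNA interference machinery, TNRC6A (-0.56) and PRKRA (-0.43) were lower and SND1 (0.44) and TNRC6B (0.35) were higher, 12 of 16 did not pass, and adjusted over the list alone 2 were higher and 3 lower. That list was not called (median 0.04, mean -0.0019, camera direction downward, adjusted p = 0.98).

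In the list for the unfolded protein response in the endoplasmic reticulum, 6 of 19 measured members were higher, 0 were lower and 13 did not pass, with a median log2 difference of 0.26 (camera adjusted p = 0.00019). Camera at an estimated correlation of 0.12 lost the call (adjusted p = 0.58). Fry, with its different question, gave an adjusted p of 0.041. Adjusted over the list alone, 9 were higher and 0 lower. SDF2L1 (0.53), the stress sensor gene ATF6 (0.52), CRELD2 (0.51) and the chaperone gene CALR (0.49) were the members with the smallest p. In the lysosome and autophagy list, 4 of 21 members were higher, 0 were lower and 17 did not pass, with 7 higher and 0 lower adjusted over the list alone. The 4 higher over all probes were the cathepsin genes CTSZ (0.72), CTSD (0.53) and CTSB (0.41) and the autophagy kinase gene ULK1 (0.54). The lysosome list had a median of 0.10 and passed narrowly (camera adjusted p = 0.034). Camera at an estimated correlation did not call it (adjusted p = 0.56), although that correlation, 0.0041, lay below the preset 0.01. The lysosome list also did not pass without siControl replicate 2 (camera adjusted p = 0.058) or siControl replicate 4 (camera adjusted p = 0.11).

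Called genes of the integrated stress response lay in both directions. The amino acid transporter genes SLC7A5 (0.73) and SLC3A2 (0.34) were higher and the serine synthesis and one-carbon genes PSAT1 (-0.52) and SHMT2 (-0.34) lower, 18 of 22 did not pass, and adjusted over the list alone 3 were higher and 4 lower (median 0.03, camera adjusted p = 0.95). Of 14 heat shock chaperones 0 were higher and 0 lower by either adjustment (median 0.07, camera adjusted p = 0.43). Of 18 NRF2 target genes the malic enzyme gene ME1 was higher (0.49) and PGD, of the pentose phosphate pathway, lower (-0.78), with the same counts adjusted over the list alone. The NRF2 list had a median of -0.01 (camera adjusted p = 0.81). In the angiogenesis and hypoxia list 4 of 21 were higher, namely ADM (0.67), P4HA2 (0.55), ANGPTL4 (0.42) and NDRG1 (0.39), and 0 were lower, with 5 higher and 0 lower adjusted over the list alone (median 0.02, camera adjusted p = 0.43).

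No list of sterol or fatty acid genes passed its test. Of 20 measured genes of cholesterol synthesis and uptake, PMVK, of the mevalonate pathway, was higher (0.48, adjusted p = 0.012) and MSMO1, a sterol methyl oxidase gene, lower (-0.33, adjusted p = 0.043), 18 did not pass, and adjusted over the list alone 2 were higher and 1 lower. The list had a median of -0.09 (camera adjusted p = 0.43). Of 11 LXR target and sterol efflux genes 0 were higher and 0 lower by either adjustment (median -0.03, camera adjusted p = 0.80). Among 20 genes of intracellular sterol transport the oxysterol-binding protein family members OSBPL5 (0.73), OSBPL2 (0.61) and OSBP (0.44) were higher, and GRAMD2B, a relative of GRAMD1B, was lower (-0.38), with the same counts adjusted over the list alone. The sterol transport list was not called (median 0.08, camera adjusted p = 0.43). In fatty acid synthesis, the elongase genes ELOVL1 and ELOVL6 and the desaturase gene FADS1 were lower and ME1 was higher, 12 of 16 did not pass, and adjusted over the list alone 2 were higher and 4 lower. The log2 differences were -1.02 for ELOVL1, -0.74 for ELOVL6 and -0.51 for FADS1. The fatty acid list did not pass (median -0.09, camera adjusted p = 0.063), but it passed downward without siControl replicate 2 (median -0.14, adjusted p = 0.014) or siGRAMD1B replicate 3 (median -0.08, adjusted p = 0.039) and with the deposited normalized values (median -0.06, adjusted p = 0.041). Its median was -0.04 without siControl replicate 4 (adjusted p = 0.18) and also -0.04 without siGRAMD1B replicate 4 (adjusted p = 0.12).

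In the drug efflux and taxane metabolism list, 3 of 14 measured members were higher and 1 was lower, and 4 were higher and 2 lower adjusted over the list alone (median 0.08, camera adjusted p = 0.43). ABCC3, an organic anion transporter of the multidrug resistance protein family, was 2.11-fold higher (log2 1.08 ± 0.11 SE, adjusted p = 3.98e-06), and CYP1B1, a cytochrome P450 gene, 1.90-fold higher (log2 0.92, adjusted p = 1.40e-05). CYP1B1 was dim in the siControl arrays (6.60, 6.64 and 6.52), and its log2 difference ran from 0.66 to 1.26 over the alternatives, so its fold is uncertain. The hepatic uptake transporter gene SLCO1B3 was lower (-0.35, adjusted p = 0.042). ABCB1, which encodes the drug pump P-glycoprotein, was 1.51-fold higher by 1 probe (from 11.53 ± 0.35 to 12.12 ± 0.26, SD, n = 3, adjusted p = 0.023) and 1.33-fold higher by the other, which did not pass (adjusted p = 0.077). At each ABCB1 probe only 2 of the 3 siGRAMD1B arrays exceeded all siControl arrays. The first ABCB1 probe did not pass without siControl replicate 1 (adjusted p = 0.062), siControl replicate 2 (0.10), siGRAMD1B replicate 2 (0.080) or siGRAMD1B replicate 3 (0.12), nor with median centring (0.092), the offset of 16 (0.16) or the ordinary test per probe (0.37). The other probe passed without siControl replicate 4 (0.0068), with trend and robust options (0.040) and with array weights (0.038), while its log2 difference of 0.41 became 0.24 without siControl replicate 2 (adjusted p = 0.31). Of 20 tubulins and microtubule regulators, TUBB was lower (-0.50) and TUBA4A higher (0.39), 18 did not pass, and adjusted over the list alone 1 was higher and 2 lower (median -0.02, camera adjusted p = 0.45).

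No list of cell survival or division genes was called by camera. Of 22 pro-apoptotic genes, BBC3 was higher (0.34) and FAS lower (-0.41), and adjusted over the list alone 3 were higher and 2 lower (median 0.02, camera adjusted p = 0.98). FAS did not pass without siControl replicate 1 (-0.27, adjusted p = 0.23) or without any 1 of the siGRAMD1B arrays (adjusted p between 0.089 and 0.14), and over all alternatives its call was lost in 9 of 18 and that of BBC3 in 10 of 18. Of 10 anti-apoptotic genes only BIRC5, which encodes survivin, was higher (0.42), by either adjustment, and 0 were lower (median 0.07, camera adjusted p = 0.65, fry adjusted p = 0.046). Of 22 p53 target genes, the DNA repair gene XPC (0.85) and BBC3 were higher and CCNG1 (-0.49), SESN1 (-0.44) and FAS were lower, with 3 higher and 3 lower adjusted over the list alone. The p53 list had a median of 0.02, a mean of 0.01 and a downward camera direction that did not pass (adjusted p = 0.98). In the list of 28 G1/S and DNA replication genes, CCND1, which encodes cyclin D1, was lower (-0.44) and 0 were higher by either adjustment (median 0.11, camera adjusted p = 0.25). Of 28 G2/M and mitosis genes the checkpoint gene MAD2L1 (-0.57) and the kinase gene PLK1 (-0.40) were lower and BIRC5 was higher, with 1 higher and 4 lower adjusted over the list alone (median -0.03, camera adjusted p = 0.43). Of 21 MYC target and ribosome biogenesis genes, NOLC1 was higher (1.00) and LYAR (-0.44), ODC1 (-0.44), RRP9 (-0.41) and 1 more were lower, with 1 higher and 5 lower adjusted over the list alone (median -0.06, camera adjusted p = 0.18).

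Of 19 measured collagen and extracellular matrix genes 6 were higher, among them THBS1 (1.04), COL4A1 (0.66), TNC (0.57) and LAMB3 (0.45), 0 were lower and 13 did not pass, with 7 higher and 0 lower adjusted over the list alone. The matrix list had a median of 0.00 and was not called (camera adjusted p = 0.25). Of 21 mesenchymal genes, MMP9 (0.59), CCN1 (0.52) and ACTA2 (0.38) were higher and CDH2, which encodes N-cadherin, lower (-0.38), with 4 higher and 2 lower adjusted over the list alone (median 0.10, camera adjusted p = 0.80). Of 12 epithelial genes 0 were higher and 0 lower by either adjustment (median -0.02, camera adjusted p = 0.80).

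**Figure D2:**
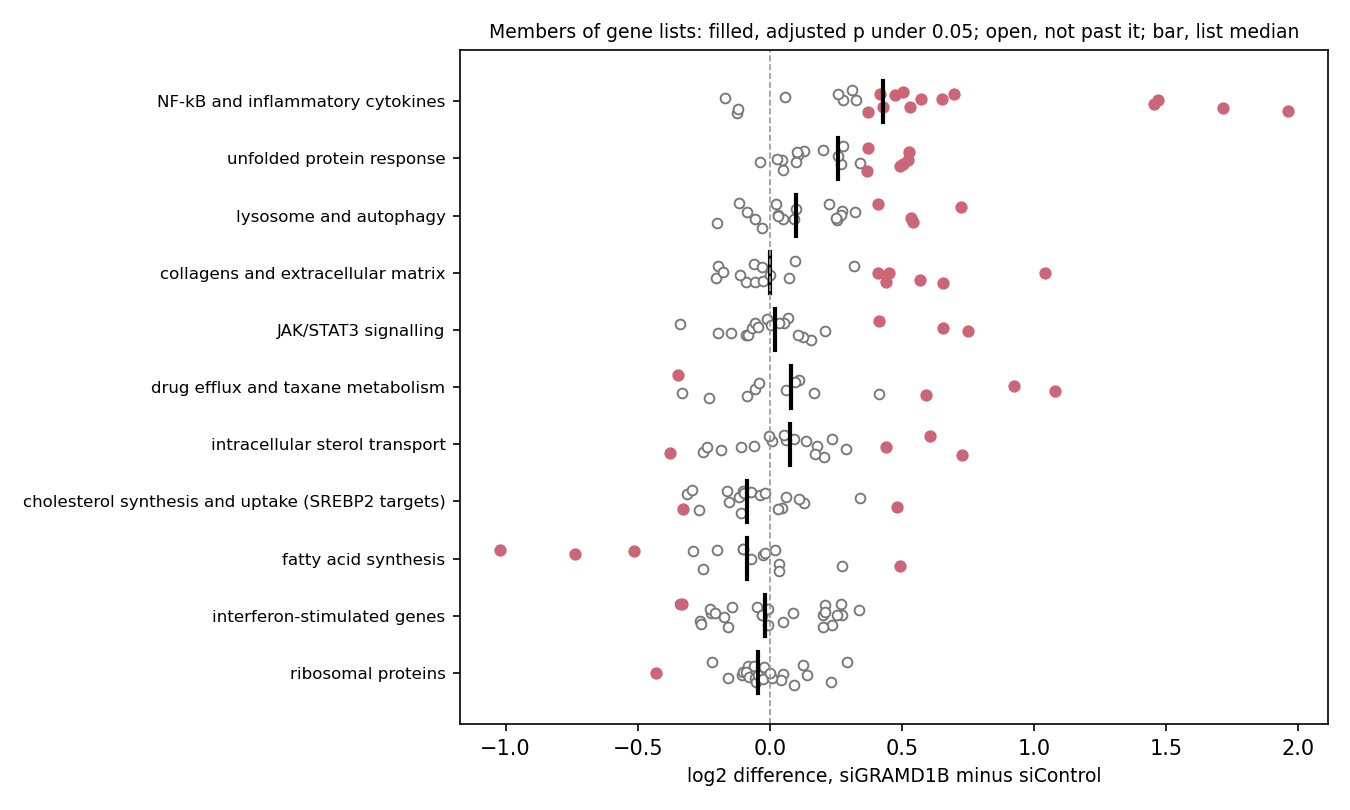
Log2 difference between siGRAMD1B and siControl (horizontal axis) for each measured member of 11 gene lists (rows, with vertical scatter added for visibility only). Filled points passed an adjusted p of 0.05 over all probes, open points did not, and the black bar is the list median, which was 0.43 for the NF-kB list, 0.26 for the unfolded protein response and -0.02 for interferon-stimulated genes.

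Constitutive genes and markers of other cell types had list medians between -0.04 and 0.10, and none of these lists was called. Of 23 ribosomal protein genes RPL13 was lower (-0.43) and 0 were higher by either adjustment (median -0.04, camera adjusted p = 0.66). Of 13 common reference genes PPIA was lower (-0.40) and 0 were higher by either adjustment (median -0.03, camera adjusted p = 0.43). Of 19 oxidative phosphorylation genes 0 were higher and 0 lower by either adjustment (median 0.01, camera adjusted p = 0.98). Among 9 leukocyte markers CD68, a lysosomal protein gene also expressed outside leukocytes, was higher (0.37, median of the list -0.02, camera adjusted p = 0.92). Of 8 endothelial markers ROBO4 (0.68) and VWF (0.38) were higher (median 0.10, camera adjusted p = 0.43). The VWF probe was dim, with a siControl mean of 6.12, and its call was lost in 10 of 17 alternatives, with values from 0.24 with the deposited normalized values to 0.66 with the offset of 16. Of 7 fibroblast markers ACTA2 alone was higher (median -0.0045, mean 0.03, camera adjusted p = 0.98). In each of these lists of other cell types 0 members were lower, and the counts were the same adjusted over the list alone. No list passed with an estimated correlation, whose smallest adjusted p was 0.073. Of the single genes given as higher or lower above, ISG20, SLCO1B3, TNRC6B, BBC3, MSMO1, SHMT2, SLC3A2, VWF, ACTA2, CD68, FAS, PPIA, RRP9, TUBA4A, GRAMD2B, OSBP, PLK1, ABCB1, BCL3, CDH2, ODC1 and SESN1 lost their call in 7 to 12 of the alternatives. The other 43 named probes that lost their call did so in 1 to 6.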

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

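An offset of 16 and a filter at the 70th percentile were chosen after the data were seen, and the other alternatives before. The planned normexp setting with an offset of 50 is the one reported, no file names a chip or slide that could serve as a block, and camera has no form that uses the ordinary test per probe, so these were not run. Against 1101 probes higher and 909 lower, a threshold of 0.01 gave 541 and 346, a threshold of 0.1 gave 1550 and 1371, median centring gave 603 and 419, the offset of 16 gave 449 and 234, and the ordinary equal-variance test per probe gave 164 and 92. Leaving out 1 array gave 673 to 1131 higher and 473 to 1007 lower, on fewer arrays. The cause of these shifts was not tested. No probe called both in the reported setting and in another changed sign. Of the 24 probes with the largest rise or fall, 18 kept their call under all 18 alternatives of values, filter, test and arrays, and 6 lost it, only under the ordinary test. Over all 93 named probes called in the reported setting, list members included, 28 kept their call under every alternative run on them and 65 lost it under at least 1, in 306 of 1673 values.

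The GRAMD1B difference stayed negative and did not pass under any setting, from -0.43 with the offset of 16 to -0.16 with the deposited values (adjusted p from 0.11 to 0.45); the filter at the 70th percentile removed the probe. With an estimated correlation 0 lists were called, with the same medians of 0.43 for the NF-kB list, 0.26 for the unfolded protein response and 0.10 for the lysosome list; the first 2 were called under every other setting. The lysosome list was also lost with a filter at the 50th percentile (median 0.10, adjusted p = 0.053), array weights (0.11, adjusted p = 0.059), the offset of 16 (0.13, adjusted p = 0.069), the filter at the 70th percentile (0.16, adjusted p = 0.085), and without siControl replicate 2 or 4, its median lying between 0.084 and 0.14 without 1 array. The fatty acid list, not called in the reported setting, was the 1 list called downward with no background correction, median centring, the deposited values, no filter or the replicate block, while leaving out 1 array gave 0 or 1 such list. The cause was not tested.

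The groups share only the replicate numbers 2 and 4, and deviations from the group means correlated at 0.03 and -0.32 between arrays of the same number. These values gave no sign that the numbers pair the arrays, but so few cannot exclude it. The other numbers occur in 1 group only, so with the replicate block the differences rested on the arrays numbered 2 and 4 alone. That setting leaves 1 residual degree of freedom, and 578 probes were higher and 409 lower. On those arrays the matrix gene COL1A1, which did not pass in any setting, had a difference of 0.0043 in place of -0.088. Signal over background limits what dim probes can show.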

Other observations

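The genes of this paragraph lie outside the rule for named genes and were chosen after their values were seen. The acute-phase genes SAA1 and SAA2, which encode serum amyloid A, were higher at all their tested probes, with log2 differences of 1.47, 1.16 and 0.78 for SAA1 and 1.39 for SAA2. TRAF1, an adaptor of tumour necrosis factor receptors, was higher by 1.04 and 0.42 at its probes (adjusted p = 4.76e-06 and 0.016). WNT5A, which encodes a secreted Wnt ligand, was higher by 0.97 (adjusted p = 2.06e-05), and both probes of the Wnt antagonist gene DKK1 were lower, at -0.44 and -0.77 (adjusted p = 0.0083 and 0.00055). EMC6, a subunit of the membrane protein insertase of the endoplasmic reticulum, was higher at 3 probes (1.07, 0.99 and 1.13), and the stress granule gene G3BP2 at 3 probes (1.09, 1.09 and 1.10). The cyclin-dependent kinase inhibitor gene CDKN1C was lower (-0.90, adjusted p = 1.19e-05), as was GJA1, which encodes the gap junction protein connexin 43 (-0.79, adjusted p = 5.17e-05). A pair of RPL34 probes disagreed, with -1.03 at 1 (adjusted p = 5.67e-06) and 0.26 at the other (adjusted p = 0.15).

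Of the tests below, those on interferon-stimulated genes, on the GRAMD1B probe and on the splits by number of probes were chosen after the results they concern had been seen. Splitting the 6 arrays into 3 and 3 gives 10 splits, too few for a share under 0.05. The real split called 2010 probes and the highest of the others 0, and it called 3 lists by camera where the highest of the others called 2. In each case 1 of the 10 splits, the real one, gave as many. The other splits called 1, 1, 2, 2, 1, 0, 1, 0 and 1 lists by camera, each with 0 probes called. Each of the other splits put 2 arrays of 1 real group and 1 array of the other on each side. Part of any real difference thus stayed in their contrast, and the rest widened the spread within their sides. Their 0 called probes are therefore not a count expected without a group difference. Which lists they called is not given here, so they do not show whether camera calls lists without the real grouping.

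The pattern weighed first is the upward shift of the list of NF-kB and inflammatory cytokine genes. Background correction or normalization as the whole cause is argued against by the list's median, which was at least 0.38 under the 5 other ways of making the values (camera adjusted p at most 1.45e-09). A rise carried by 1 array is argued against by a median of at least 0.39 without any of the 6 arrays. An interferon response to the siRNA, of the size of the NF-kB change, is argued against only for the list as a whole. Its bright and dim members were not tested apart. The median of 26 interferon-stimulated genes was -0.018, below the NF-kB median of 0.43 by more than the SD of those genes (0.21). The interferon list was dimmer, with a median level of 7.29 against 8.89 for the NF-kB list. Rises at its dim members would be understated, so a response carried by them is not excluded. Loss of GRAMD1B, an effect of the siRNA on other transcripts, and a chip or day shared within a group were not tested and stay open, and the call does not hold with an estimated correlation (adjusted p = 0.073).

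The other pattern is the small difference at the GRAMD1B probe. A candidate explanation is a signal close to the floor, which compresses fold changes. The siGRAMD1B mean lay at the 48.7th percentile of all probes, as this needs, but the difference grew only 1.72 times when the offset was lowered from 50 to 16, less than the doubling set as the bound, so the test did not decide. In simulated data, changes of dim probes by 1.5-fold, 2-fold and 3-fold were fitted with medians of 0.21, 0.38 and 0.54 on the log2 scale. These medians pool rises and falls by size, whatever the fitted sign, and a fall removes less signal than an equal rise adds. They are thus no yardstick for the fall at the GRAMD1B probe. A weak knockdown and the floor cannot be told apart with this probe.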
